A study of Mus musculus with 6 samples.

How the data were processed

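RNA from epithelial cells of the small intestine in 6 samples from mice aged 14 days was hybridized to Affymetrix mouse expression arrays, 1 array per sample, with 3 control and 3 N-cadherin replacement samples grouped by their labels. The deposited table holds linear probe set intensities for 45101 probe sets, which the authors had scaled before deposit, as the values show: the mean without the lowest and highest 2% was 100 on every array. Per the submitters' processing notes GCRMA and limma were used, with no version or order, and the summary method behind these intensities is not given in the sources used here. GCRMA writes log2 values, which was the unit planned for, and the deposited intensities are not on that scale. The values were therefore floored at 16, the intensity that corresponds to the planned filter of 4 on the log2 scale, and log2 was taken. A floor compresses differences of dim transcripts, so where every array of a group lay at the floor the fold is given as a bound ("at least"), as it is, with the number of arrays, where only some arrays of the lower group lay under it. The table held 28 zeros, all under the floor. For arrays no read depth exists, and the number of arrays limits the precision.

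A probe set was kept where at least 3 of the 6 arrays reached 16, which left 26664 probe sets (59.1%). Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several, 9160 were not named there and 64 were Affymetrix controls. By Entrez identifier 34741 of those with 1 symbol matched the gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. Of the kept probe sets 22603 had 1 gene, and the probe set with the highest mean over all arrays stood for its gene, which gave 12994 genes; no gene among the 30 that changed most had probe sets of opposite direction. Among those 30 genes, probe sets that may cross-hybridize, by the suffix of their name, are reported as uncertain. This was not done for every other gene.

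Replicates were compared before averaging. Control 2 and control 3 differed over 5109 probe sets with at least 200 intensity units on all arrays by an SD of 0.115 on the log2 scale, where 18 hybridization control probe sets gave 0.0824 for the same pair. Other pairs within a group gave 0.347 to 0.564 and pairs between groups 0.528 to 0.733. Their log2 values were averaged and counted as 1 replicate, since the SD lay within the range of the hybridization controls over all pairs (0.0812 to 0.134) though over their value for this pair. This departs from the planned fit with all 6 arrays, which is given as an alternative. The fit used limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options) on 2 control and 3 replacement replicates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are replacement minus control on the log2 scale. An SE is that of the moderated fit, so it shares the spread across genes. Where every array of a group lay at the floor, that group showed no spread. The SE and p then rest on the other group and on the spread shared across genes.

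Fixed lists of genes for pathways, junctions, epithelial lineages and other cell types that the detached fraction could hold were tested where at least 5 members were measured, 38 lists in all. The test was camera in limma with a preset correlation of 0.01 between genes, adjusted over those lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. In the text an adjusted p beside a list is from camera with the preset correlation unless an estimated correlation is named. Named genes are Cdh1 and Cdh2, the 15 genes with the largest difference in each direction among those past the threshold whose arrays did not overlap between the groups, and up to 4 members with the smallest p of each list. These rules, the lists, the tests and most alternatives were fixed before the data were examined; other genes are said to be chosen after their values were seen. Figures were drawn with matplotlib 3.10.9.

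The steps were tested on simulated data with 12994 genes, of which 200 were changed, with 2 control and 3 replacement replicates. The members of the desmosome list were raised by 1 as well. At a log2 difference of 1 the steps recovered 3% of the changed genes among the 200 and at 2 they recovered 61%, with 2 unchanged genes called. In the data 1185 genes were called, and the adjustment grows less strict as more genes pass. The shares recovered therefore do not carry over to the data.

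Alternatives were other eBayes options, no filter or a filter at 64, quantile normalization, scaling to the array medians, the mean of all probe sets of a gene, every probe set, array weights, the replicate number as a block, each array left out in turn, a 2-fold limit, a test against 1.5-fold and a fit without eBayes. Added after the data were seen were control 2 and control 3 as separate replicates, no floor (with 0 set to 0.1), a pseudocount of 16, sex as a block, control 2 and control 3 left out together, and a window of 100 gene positions around Cdh1. Samples were put into sexes by Xist and Eif2s3y, since the labels do not give it.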

Results

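Transcript levels were measured with Affymetrix mouse expression arrays in epithelial cells detached from the small intestine of C57BL/6 mice aged 14 days. In 3 of the 6 samples, called N-cadherin replacement here, the epithelium carried N-cadherin (Cdh2), a cadherin typical of neural and mesenchymal cells, in place of E-cadherin (Cdh1), the main adhesion molecule of the adherens junctions between epithelial cells. A floxed allele and Vil-Cre, a recombinase active in gut epithelium, brought about the exchange. The other 3 samples, called control, came from littermates that kept E-cadherin. Their genotype is not given beyond this, so whether they carried the floxed allele, Vil-Cre or the N-cadherin allele is unknown here. Each array gave 45101 probe set intensities, and the mean without the lowest and highest 2% of values was 100 on every array. Between 55.1% and 61.8% of the probe sets of an array reached an intensity of 16, the floor used here. Control 2 and control 3 differed little: the SD of their log2 ratio over 5109 bright probe sets was 0.115, whereas other pairs within a group gave 0.347 to 0.564. As a measure of array noise, 18 hybridization control probe sets gave 0.0824 for this same pair, which is less, and 0.0812 to 0.134 across the array pairs. These arrays thus differed by an amount within the range of that noise, though not under its value for the pair, and were counted as 1 sample, which left n = 2 control and n = 3 replacement replicates. The labels do not say whether each sample came from a separate animal, so p-values measure the spread between these samples, and the number of arrays limits the precision. A group whose arrays all lay at the floor adds no spread of its own to them.

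The comparison asked which transcripts differ when the epithelium carries N-cadherin and lacks E-cadherin. Cdh1 had intensities of 2757, 2335 and 2204 in the control arrays and of 1073, 1175 and 1357 in the replacement arrays, a log2 difference of -1.06 (SE 0.240, n = 2 and 3), which is 2.09-fold lower (limma adjusted p = 0.0250). The annotation does not say whether this probe set lies in the deleted part of the gene. The number of working Cdh1 copies in the controls is not given either. The remaining signal therefore checks the labels only in part. Both Cdh2 probe sets stayed under the floor on all 6 arrays, with 13.5 as the highest intensity, and no fold is given. Whether the introduced copy holds the sequence they read is not given in the sources used here. The Cdh1 call was lost when control 1 was left out (log2 difference -0.92, adjusted p = 0.213), when control 2 and control 3 were left out together (-1.21, adjusted p = 0.162), without replacement 2 (-1.05, adjusted p = 0.0825) and without replacement 3 (-1.16, adjusted p = 0.0714). It was also lost with scaling to the array medians (-1.03, adjusted p = 0.0589) and with no filter on dim probe sets (-1.06, adjusted p = 0.109).

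Across 12994 genes, 580 were higher and 605 lower in the replacement samples at a limma adjusted p under 0.05, together 9.12% of the genes tested, and 516 and 536 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 1482 higher and 1677 lower genes. The median difference over all genes was -0.02 on the log2 scale. In 36.6% of the genes the arrays of the groups did not overlap, against 20% by chance for 2 and 3 replicates. The first principal component held 62.0% of the variance and separated the groups. The counts depended on the few control replicates: 8 higher and 3 lower genes passed without control 1, and 3 and 1 without control 2 and control 3, fits in which the lone control replicate is assumed to vary like the others. With control 2 and control 3 as separate replicates 1118 genes were higher and 1234 lower. The counts were 272 and 261 without replacement 2 and 207 and 167 without replacement 3. Of the 107 called genes among the 192 that the naming rule covers, 98 lost the call without control 1, 104 without control 2 and control 3, 42 without replacement 2 and 57 without replacement 3.

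The 15 genes that rose most had log2 differences of 3.97 or more. Anxa10, a member of the annexin family, was under the floor in every control array and had a geometric mean intensity of 2507 in the replacement arrays, at least 157-fold higher (log2 difference at least 7.29, SE 0.223, adjusted p = 5.93e-07). Anxa1, of the same family, rose 21.9-fold, from 118 to 2588 (log2 difference 4.45, SE 0.244, adjusted p = 2.77e-05). Sptssb, a small subunit of serine palmitoyltransferase, the enzyme that starts sphingolipid synthesis, was at least 56.9-fold higher, and Il1rn, the interleukin-1 receptor antagonist, at least 40.2-fold higher, both from control levels under the floor. Ly6d, a lipid-anchored surface protein, was above the floor in 1 of 3 control arrays (37.3) and had a geometric mean of 2289 in the replacement arrays. With the other control arrays set to the floor its log2 difference was at least 6.55 (SE 0.412, adjusted p = 4.76e-05). It was at least 7.16 without control 1, where both arrays left were under the floor, and 5.94 without the other control replicate. The glutathione S-transferase Gsta4 rose 34.3-fold and Clu, the secreted chaperone clusterin, 26.7-fold. Clu was read by a probe set whose suffix marks possible cross-hybridization, and its 4 probe sets gave log2 differences of 4.74 to 6.52. The membrane protein Pmp22 rose 25.0-fold and Ada (adenosine deaminase) 22.9-fold. F3 (tissue factor, the initiator of coagulation), which was above the floor in 1 of 3 control arrays (27.3), was at least 22.3-fold higher. Mboat1, an acyltransferase of lysophospholipids, rose 19.0-fold and the actin-capping protein Capg 18.6-fold. Other probe sets of some of these genes gave smaller log2 differences in the same direction. The smallest were 1.64 for Mboat1, 1.85 for Capg, 3.69 for Anxa10, 3.66 for Sptssb, 2.63 for Il1rn and 2.54 for Ano1. Oit1 rose 16.3-fold. S100a14 was at least 18.4-fold and the calcium-activated chloride channel Ano1 at least 15.7-fold higher, each with 2 of 3 control arrays at or above the floor, and the probe set of Ano1 may be shared by related transcripts. Ada differed within the control group, at 263 in control 1 and near 77 in control 2 and control 3 (78.7 and 75.4), and its log2 difference was 5.40 without control 1 and 3.63 without the other control replicate, against 4.52 with all.

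**Figure D1:**
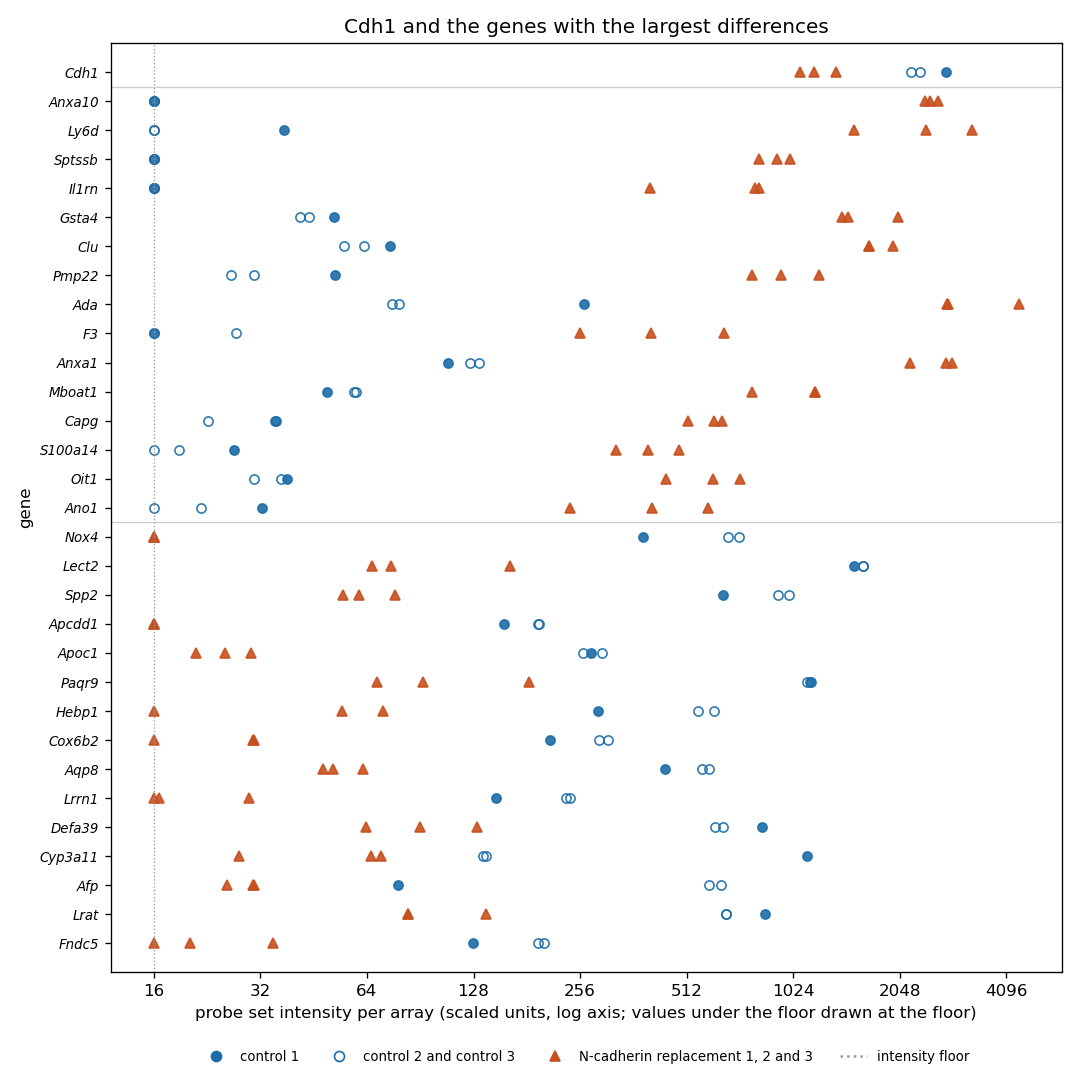
Probe set intensity on each array (scaled units, log axis) for Cdh1, the 15 genes that rose most and the 15 that fell most, with 1 marker per array: filled circles for control 1, open circles for control 2 and control 3, triangles for N-cadherin replacement. Values under the floor of 16 are drawn at the floor, and in every gene shown the replacement arrays lie on one side of the control arrays.

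The 15 genes that fell most had log2 differences of -2.83 or beyond. Nox4, an NADPH oxidase that forms hydrogen peroxide, had a geometric mean intensity of 517 in the control arrays and was under the floor in every replacement array, at least 32.3-fold lower (log2 difference -5.01 or beyond, SE 0.284, adjusted p = 2.99e-05). Lect2, a secreted protein, went from 1565 to 93.0, which is 16.8-fold lower (log2 difference -4.07, SE 0.369, adjusted p = 4.02e-04), and Spp2, a secreted phosphoprotein, was 12.4-fold lower. Apcdd1, a membrane inhibitor of Wnt signalling, was under the floor in every replacement array and at least 10.9-fold lower. Its probe set may cross-hybridize, its 5 probe sets gave log2 differences of -3.45 to -1.29, and its call was lost with no floor. Apoc1, an apolipoprotein, was 10.9-fold lower, as was the membrane receptor Paqr9 (10.9-fold). The water channel Aqp8 was 9.48-fold lower and Lrat, which esterifies retinol for storage, 7.57-fold lower. Other probe sets gave log2 differences of -1.54 for Lrat, -3.05 for Paqr9 and -4.14 for Nox4. The heme-binding protein Hebp1 was at least 10.3-fold, the cytochrome c oxidase subunit Cox6b2 at least 10.2-fold, Lrrn1 at least 9.43-fold and Fndc5 at least 7.10-fold lower, each with 2 of 3 replacement arrays at or above the floor. Replacement 1 was the array of Hebp1 under the floor, and without it the log2 difference of Hebp1 was -2.71, against -3.37 with all. Defa39, an alpha-defensin, was 7.98-fold lower, but its probe set may be shared by other members of that family. Cyp3a11, a drug-metabolizing cytochrome P450, and Afp (alpha-fetoprotein) had log2 differences of -2.96 (SE 0.741, adjusted p = 0.0380) and -2.93 (SE 0.664, adjusted p = 0.0257), with control levels that ran in opposite directions: Cyp3a11 stood at 1120 in control 1 against 138 and 136, Afp at 78.5 in control 1 against 639 and 592. Leaving out one control replicate or the other gave -1.44 or -4.47 for Cyp3a11 and -4.41 or -1.44 for Afp, and of 19 alternatives 9 ended the call of Cyp3a11 and 7 that of Afp.

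Of 5 lists of epithelial attachment 3 passed with the preset correlation and none with an estimated one. With the preset correlation the 9 other splits of the replicates called 3 to 15 lists. A list call of that kind alone therefore does not set the real groups apart. In the desmosome list, the keratin-anchored junctions between epithelial cells, 6 of 14 measured members rose and none fell, or 10 adjusted over the list alone. The keratins Krt7 and Krt19 rose by 2.63 (SE 0.272) and 1.27 (SE 0.232) on the log2 scale, Ppl by 1.54 (SE 0.237) and Pkp2 by 1.38 (SE 0.255). Dsc2 (1.19) and Pkp3 (1.05) rose too. Dsp (0.14), Dsg2 (0.66), Jup (-0.04) and Perp (-0.05) did not pass over all genes, so the rise did not cover every listed gene. The mean difference of the list was 0.97 (camera adjusted p = 3.59e-06), with an adjusted p = 0.520 with an estimated correlation. In the tight junction list 2 of 19 members rose, Cldn3 (1.07, SE 0.236) and Cldn23 (1.02, SE 0.245), or 3 adjusted over the list alone, and 17 of 19 differences were above 0. Its mean was 0.35 (adjusted p = 0.0189), with an adjusted p = 0.520 with an estimated correlation. In the basement membrane adhesion list 3 of 14 members rose and 1 fell, or 5 and 1 adjusted over the list alone. Lamb3, a laminin chain of epithelial basement membranes, rose by 2.96 (SE 0.245), the laminin chain Lama5 by 0.94 (SE 0.242) and the integrin chain Itgav 1.996-fold, while Dst, which links hemidesmosomes to the cytoskeleton, had -1.49 (SE 0.256). The list mean was 0.45 (adjusted p = 0.0286, and adjusted p = 0.520 with an estimated correlation), and this call was lost without replacement 1 (0.43, adjusted p = 0.0850) and with a filter at 64 (0.42, adjusted p = 0.0887). Among 13 adherens junction genes Cdh1 alone passed, also adjusted over the list alone, and the list mean was 0.01 (adjusted p = 0.684). Of the 14 genes of the epithelial-mesenchymal transition list 8 were measured and none passed, and the list mean was -0.23 (adjusted p = 0.646). Within the samples that sex-linked genes put among females its mean was -0.78, and within males 0.45, each from 1 control replicate. The fibroblast list had opposite signs too (-1.30 and 0.61). With such a split between single replicates, the pooled mean does not settle whether these genes changed.

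Cholesterol synthesis gave the smallest p of the 38 lists tested. All 16 measured members had differences above 0 and 9 of them rose, or 13 adjusted over the list alone, with a list mean of 1.45 (camera adjusted p = 1.90e-11, and adjusted p = 0.520 with an estimated correlation). Cyp51 rose from 107 to 710 (log2 difference 2.73, SE 0.273), Sqle from 115 to 735 (2.67, SE 0.272) and Fdps from 129 to 746 (2.53, SE 0.260), 3 enzymes of the sterol pathway. Mvk, under the floor in all control arrays, rose by at least 2.00. In the cell cycle list 6 of 26 members rose, or 16 adjusted over the list alone, and 25 of 26 differences were above 0. Rrm2, a subunit of ribonucleotide reductase, rose by 1.59 (SE 0.270), Cdc20, an activator of mitotic exit, by 1.47 (SE 0.267), Ccna2 (cyclin A2) by 1.39 (SE 0.267) and the replication helicase subunit Mcm5 by 1.42 (SE 0.274). The list mean was 0.85 (adjusted p = 5.26e-10), and the call was lost with an estimated correlation (adjusted p = 0.520) and with fry (adjusted p = 0.0626).

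In the list of receptor tyrosine kinase output 4 of 14 members rose, or 7 adjusted over the list alone: Dusp4 (2.01, SE 0.248), a phosphatase that limits MAP kinases, Ereg (2.64, SE 0.337), a ligand of the EGF receptor, Phlda1 (1.65, SE 0.328) and Spred1 (1.04, SE 0.252). The list mean was 0.80 (camera adjusted p = 3.24e-04), and the call was lost with an estimated correlation (adjusted p = 0.574) and with fry (adjusted p = 0.0973). The YAP target and fetal epithelium list split: 6 of 12 members rose and 2 fell, or 6 and 4 adjusted over the list alone. Clu and Anxa1, described above, rose most, followed by Il33 (3.53, SE 0.477, but 4.52 without control 1 and 2.53 without the other control replicate), an alarmin cytokine, and Anxa3 (2.72, SE 0.251). The list mean was 1.15 (adjusted p = 0.0342, and adjusted p = 0.574 with an estimated correlation), and this call was lost without replacement 1 (1.20, adjusted p = 0.0599) and without control 2 and control 3 together (0.95, adjusted p = 0.157), with no filter (1.15, adjusted p = 0.102) and with a filter at 64 (1.26, adjusted p = 0.147).

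The lists of crypt signalling did not pass. Of 16 Wnt target genes 4 rose and 2 fell, or 4 and 3 adjusted over the list alone, with a list mean of 0.12 (adjusted p = 0.646): Cd44, a hyaluronan receptor, rose by 3.04 (SE 0.334) and Sox4 by 1.36 (SE 0.249), while the secreted Wnt inhibitor Notum had -0.97 (SE 0.240). Among 13 intestinal stem cell genes Prom1 alone rose (2.50, SE 0.288), also adjusted over the list alone, and Lgr5 (-0.53, SE 0.264) and Olfm4 (-0.42, SE 0.235) did not pass. This list had a mean of 0.13, a median of -0.18 and an adjusted p of 0.818. In the Notch pathway list the ligand Jag1 rose (1.01, SE 0.240) and the ligand Dll1 fell (-0.94, SE 0.230) among 13 genes, the same count adjusted over the list alone, with a mean of -0.04 (adjusted p = 0.850). In the list of BMP and hedgehog genes Bmp8b rose (at least 2.32, SE 0.294, with 2 of 3 control arrays at or above the floor) and Id2, a target of BMP signals, fell (-1.69, SE 0.280), 1 and 2 of 11 adjusted over the list alone, with a mean of -0.21 (adjusted p = 0.434). Of 12 p53 target genes Phlda3 rose (1.14, SE 0.235) and Sesn2 fell (-0.96, SE 0.254), also adjusted over the list alone, with a mean of 0.13 (adjusted p = 0.584).

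Of 12 measured enterocyte genes of the suckling period 6 fell, or 9 adjusted over the list alone, and all 12 differences were below 0, with a mean of -0.79 (camera adjusted p = 9.29e-05, and adjusted p = 0.520 with an estimated correlation). Cubn and Amn, which form a receptor for endocytosis of proteins, had -1.47 (SE 0.264) and -1.04 (SE 0.238), Prdm1, a repressor that holds back the adult enterocyte program, -1.08 (SE 0.244), and the lysosomal sialidase Neu1 -1.05 (SE 0.255). In the lipid absorption list 3 of 21 members fell, or 4 adjusted over the list alone: Abcg8 (-1.33, SE 0.245) and Abcg5 (-1.28, SE 0.243), which together return sterols to the lumen, and the fatty acid transporter Cd36 (-1.24, SE 0.327). The list mean was -0.44 (adjusted p = 0.0146, and adjusted p = 0.902 with an estimated correlation), and this call was lost with fry (adjusted p = 0.302), without control 1 (-0.33, adjusted p = 0.0576) and without replacement 2 (-0.32, adjusted p = 0.0868). Within the samples that sex-linked genes put among females its mean was -0.71, and within males -0.01. In the list of PPAR-alpha and ketogenesis genes the acyl-CoA thioesterases Acot1 (-1.53, SE 0.230) and Acot2 (-1.23, SE 0.302) fell among 13 members, also adjusted over the list alone. Its mean was -0.42 (adjusted p = 0.0342, and adjusted p = 0.574 with an estimated correlation), and the call was lost with fry (adjusted p = 0.0587), without control 1 (-0.29, adjusted p = 0.106), without replacement 1 (-0.41, adjusted p = 0.0749) and with the mean of all probe sets of a gene (-0.30, adjusted p = 0.113).

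Other enterocyte lists did not pass as groups. In the enterocyte brush border list 1 of 19 members rose and 2 fell, or 1 and 4 adjusted over the list alone, with a mean of -0.39 (adjusted p = 0.0787): Krt20 rose by 1.35 (SE 0.312), and the glucose transporter Slc2a2 (-1.80, SE 0.227) and the peptidase Anpep (-1.16, SE 0.298) fell. Among 8 weaning-period genes Arg2, an arginase, rose (2.35, SE 0.499, but 3.36 without control 1 and 1.33 without the other control replicate) and Cyp3a11 fell, also adjusted over the list alone, with a mean of -0.17 (adjusted p = 0.850). Of 11 proximal small intestine genes Pdx1, a duodenal transcription factor, alone rose (at least 2.05, SE 0.371, with 2 of 3 control arrays at or above the floor), also adjusted over the list alone. Its difference was at least 2.72 without control 1 and 1.38 without the other control replicate. The mean of the list was 0.01, the median -0.36 and the adjusted p 0.684. Of 9 distal small intestine genes Nr0b2 (-2.06, SE 0.345) and Slc51b (-1.65, SE 0.322), which act in bile acid signalling and export, fell, also adjusted over the list alone, with a mean of -0.37 (adjusted p = 0.144). In the xenobiotic metabolism list 2 of 17 members rose, Gsta4 and Cyp2c65 (1.67, SE 0.425, but 2.50 without control 1 and 0.85 without the other control replicate), and 2 fell, Ugt2b5 (-1.68, SE 0.390) and Cyp3a11, or 3 and 2 adjusted over the list alone. The mean was 0.19, the median -0.02 and the adjusted p 0.622.

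Of 15 measured interferon response genes 3 fell, or 7 adjusted over the list alone, and all 15 differences were below 0. Those that fell were the immunoproteasome subunits Psmb9 (-1.36, SE 0.313) and Psmb8 (-1.65, SE 0.382), and Ifit1 (-1.13, SE 0.288). The mean was -0.81 (camera adjusted p = 5.05e-05), and the call was lost with an estimated correlation (adjusted p = 0.574) and with fry (adjusted p = 0.101). The list of antimicrobial and inflammation genes had 4 of 16 members up and 1 down, or 5 and 1 adjusted over the list alone, and a mean of 0.60 (adjusted p = 0.0734). The bactericidal lectin Reg3g rose from 308 to 3070 (log2 difference 3.32, SE 0.636), with 1.96 without control 1 and 4.68 without the other control replicate. Saa1, an acute phase protein, rose by at least 1.99 (SE 0.422) and Duoxa2, a maturation factor of the oxidase Duox2, at least 2.83-fold (adjusted p = 0.00883), both with 2 of 3 control arrays at or above the floor, while the chemokine Cxcl5 rose by at least 1.34 from a control level under the floor. None of 6 MHC class II genes passed, and the list mean was -0.50 (adjusted p = 0.442).

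**Figure D2:**
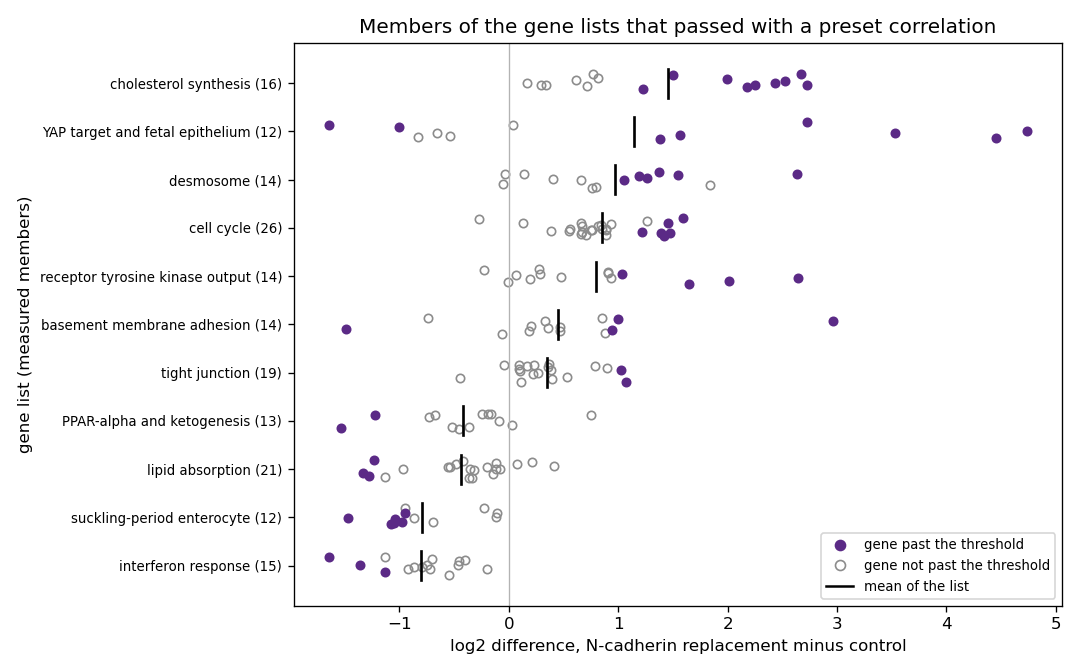
Log2 difference, N-cadherin replacement minus control, of each measured member of the 11 gene lists that passed with a preset correlation of 0.01 between genes, with filled circles for genes past the threshold, open circles for the others and a black bar at the list mean. List means run from -0.81 for interferon response to 1.45 for cholesterol synthesis, and no list passed with an estimated correlation.

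Secretory lineages gave few calls. Gip (-2.06, SE 0.531, and -2.65 without replacement 1) and Sct (-1.72, SE 0.447), hormones of enteroendocrine cells, fell among 18 genes of that list, or 3 adjusted over the list alone, with a mean of -0.50 (adjusted p = 0.105). Of the 16 listed Paneth cell genes only 7 were measured. Among these the protease Mmp7 rose (1.30, SE 0.340) and Pla2g2a, an antibacterial phospholipase, fell (-1.36, SE 0.359), also adjusted over the list alone. Lyz1 had -0.53 (SE 0.362), and the mean of the measured members was -0.23 (adjusted p = 0.664). None of 17 goblet cell genes (mean 0.08, median -0.13, adjusted p = 0.646) and none of 12 tuft cell genes (mean 0.18, adjusted p = 0.361) passed. Of 16 circadian clock genes 4 fell, also adjusted over the list alone, with a mean of -0.34 (adjusted p = 0.0734): Per2 had -1.25 (SE 0.240), Cry2 -1.03 (SE 0.257), Per1 -1.03 (SE 0.266), and Dbp -1.34 or beyond, since it lay under the floor in the replacement arrays. Of 19 genes of the list for ER stress and the unfolded protein response Asns, asparagine synthetase, rose (1.63, SE 0.239) and Ddit3 fell (-2.12, SE 0.394), or 1 and 2 adjusted over the list alone. The mean was -0.05, the median 0.05 and the adjusted p 0.883. Of 16 dissociation and immediate early genes Hspa1b rose (1.12, SE 0.225) and Egr1 (-0.91, SE 0.242) and Fosb (-1.06 or beyond, SE 0.280, with 1 replacement array under the floor) fell, or 1 and 3 adjusted over the list alone, with a mean of -0.23 (adjusted p = 0.442). None of 17 mitochondrial respiratory chain genes passed (mean -0.18, adjusted p = 0.646).

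None of the 5 tested lists for other cell types that a detached epithelial fraction could hold passed. Among 12 fibroblast genes Fbln1 fell (-1.07, SE 0.252), also adjusted over the list alone, and the mean was -0.34 (adjusted p = 0.361). None of 9 endothelial cell genes (mean -0.20, adjusted p = 0.654), 6 B and plasma cell genes (mean 0.14, adjusted p = 0.646) or 8 pancreatic acinar genes (mean 1.20, adjusted p = 0.188) passed. Of 10 myeloid cell genes Cd14 rose (2.64, SE 0.262) and Csf1r fell (-1.44, SE 0.286), also adjusted over the list alone, with a mean of -0.07 (adjusted p = 0.763). Under 5 members were measured of the lists for T cells and intraepithelial lymphocytes (4), smooth muscle (4), enteric neurons and glia (4), erythroid cells (0) and sex-linked genes (4), and these were not tested as lists. The mean log2 intensity of the 4 enteric neuron and glia genes was 5.86 and 5.82 in the control and 5.49, 5.31 and 5.17 in the replacement replicates. It was the 1 of 9 lists compared by replicate whose groups did not overlap, where chance gives 20% for each, and S100b, a glial marker among its genes, fell (-1.65, SE 0.307). The smooth muscle genes (6.66 and 6.74 against 7.03, 6.34 and 6.46) and the T cell genes (4.95 and 4.61 against 4.81, 4.54 and 5.17) overlapped. The ratio of the 3' to the 5' control probe sets lay between 0.651 and 0.774 for Gapdh, with overlapping groups. For Actb it lay between 1.30 and 1.35 in the control arrays and between 1.10 and 1.24 in the replacement arrays, which did not overlap (two-sided exact permutation test over the 10 splits of the replicates, p = 0.20, where the smallest possible is 0.10). Xist, the transcript of the inactive X chromosome, and the Y-linked Eif2s3y put control 1 and replacement 2 and 3 among females and control 2, control 3 and replacement 1 among males, with an Eif2s3y intensity of 114 in replacement 1 against 410 and 418 in the male controls. Xist stood at 440 and 578 in replacement 2 and 3 against 2305 in control 1, and at 37.5 in replacement 1 against 27.8 and 29.3 in the male controls. The labels do not say whether a sample pools animals. Eif2s3y was 2.2 and 0.9 in replacement 2 and 3, near the 0.3 of control 1, which argues against male RNA in them. Xist in replacement 1 lay near the male controls, which argues against a large female share there, though a small one is not ruled out. The reason for the lower levels is unknown, and the values by sex below are uncertain to that extent. Stomach transcripts were looked up after the genes that rose most were known. Tff1 reached 333 in a replacement array and 262 in a control array, and Gkn1, Gkn2 and Atp4b at most 26.2 in the replacement arrays. Gkn1 and Gkn2 did not pass the filter, and each was higher on every replacement array (11.8 to 19.9 and 14 to 17.5) than on every control array (at most 8 and 7.7). Of 8 measured stomach genes, with a median difference of 0.12, Ctse, a gastric protease, was the 1 that rose, from at most 59.7 to between 174.9 and 402.6 (2.61, adjusted p = 0.00297). Of 7 measured genes of squamous epithelium, looked up in the same way, Sprr1a was the 1 that rose (1.34, adjusted p = 0.0153). Of 5 measured colon genes, also looked up then, with a median difference of -0.10, Muc4 was the 1 that rose (1.49, adjusted p = 0.0109). The probe set of Muc4 may cross-hybridize. With sex as a block 637 genes were higher and 701 lower. Within females the called genes had a median difference of 1.41 in the called direction and within males of 1.24. These genes were called on the same replicates, so a median in that direction was built in and lends no separate support. Each sex held 1 control replicate, and the males held 1 replacement replicate. The mean of the cholesterol synthesis list was 1.65 within females and 1.24 within males, that of the cell cycle list 0.94 and 0.63, that of the suckling-period list -0.75 and -0.77, that of the interferon response list -1.09 and -0.36 and that of the lipid absorption list -0.71 and -0.01, and these differences between the sexes were not tested. The other 6 lists that passed had the sign of their pooled mean in both. Of 22 tested genes within 20 positions of Cdh1 in the gene order of the GRCm38.p6 annotation 2 were called (9.09%, against 9.12% of the other genes; two-sided Fisher's exact test p = 1).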

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

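The tests with sex as a block, of stromal and immune cells, of crypt cell types, of the stomach list's median and of the Actb ratio were chosen only after the results were seen; those of squamous keratins and of abundant stomach transcripts were chosen after the genes that rose most were known but before the values they measure were seen; the others were chosen before.

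Probe sets that the annotation pairs with no gene or with several are left out of the comparisons by gene. Among 4027 such probe sets past the filter, fitted on their own with limma, 2 were higher and 2 lower in the replacement samples. That is a far smaller share than the 9.12% of the named genes. The fit and its adjustment were separate from those of the named genes, so the counts cannot be compared directly. Of the higher ones, 1 lay at 17.3 to 22.3 in the control and 339.0 to 432.7 in the replacement arrays (log2 difference 4.30, adjusted p = 0.00710), and the other had a difference of 3.37 (adjusted p = 0.0218). Of the lower ones, 1 went from 938.7 or more to at most 34.1 (-5.16, adjusted p = 0.00682), with a name that marks possible cross-hybridization, and the other had -3.52 (adjusted p = 0.0459).

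The first pattern is the number of genes called, 1185. The 5 replicates can be split in 10 ways into 2 and 3, too few for a share under 0.05. For genes 1 split, the real one, gave as many calls, and the highest of the others gave 0. For gene lists the real split called 11 and the 9 others 3 to 15, and 4 splits, the real one included, called as many. The number of lists called with the preset correlation therefore does not set the real groups apart from other splits. With sex as a block 1166 of the 1185 genes were called, which argues against sex as the main source, as far as the sexes read from the data hold. Eif2s3y in replacement 1 and Xist in replacement 2 and 3 were lower than in the controls of the same sex. Eif2s3y at 2.2 and 0.9 in replacement 2 and 3 and Xist at 37.5 in replacement 1 argue against mixed pools as the reason. A small female share in replacement 1 is not ruled out. The 0.169% of calls within 20 positions of Cdh1 decides nothing about linked sequence of a donor strain, since the 22 genes tested there could reach 1.86% at most. With an estimated correlation camera called 0 lists up and 0 down. A difference in RNA quality or in handling between the groups stays open, since the Actb ratio did not overlap between them, and so does the effect of the exchanged cadherin itself.

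The second pattern is the rise of the 15 genes that rose most, by 3.97 or more on the log2 scale. A joint rise of stromal and immune cells is argued against by a median difference of -0.17 over 49 members of 7 lists (95th percentile 0.55). Within males the fibroblast list had 0.61 and the myeloid list 0.76, still far under 3.97. The pooled median could miss a rise of a single cell type. In the myeloid list, with a mean of -0.07, Cd14 rose and Csf1r fell. Squamous epithelium carried over is argued against as the source by Krt4, Krt5, Krt13 and Krt14, at most 46.9 on the replacement arrays and under the bound of 100 set beforehand. The probe sets of Krt4 and Krt13 may cross-hybridize. Sprr1a of the same list rose (1.34), and Krt6a had 0.88 (adjusted p = 0.0944). Of 4 abundant stomach transcripts Tff1 reached 333, over that bound but also over it in the control arrays (262), so the bound decides nothing, while Gkn1, Gkn2 and Atp4b were at 26.2 or less on the replacement arrays. Stomach epithelium carried over is argued against as the source of the whole rise by a median difference of 0.12 over 8 stomach genes (95th percentile 1.98), with Tff1 at 0.22, Cldn18 at -0.15, Pgc at -0.22 and Atp4b at -0.33. Ctse was higher (2.61), and Gkn3, whose probe set may cross-hybridize, had 0.81 (adjusted p = 0.0745). Gkn1 and Gkn2, near or under the floor and not in that median, were higher on every replacement array than on every control array. A contribution of stomach cells to part of the rise therefore stays open. So do a rise of a single stromal or immune cell type and a change within the intestinal epithelium.

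The third pattern is the difference of the cell cycle list, of which 6 of 26 members rose and whose call was lost with an estimated correlation (adjusted p = 0.520) and with fry (adjusted p = 0.0626). An even increase of all crypt cell types would raise stem cell and Paneth cell genes with it, but their median difference was -0.18 over 20 members, against 0.83 over 26 cell cycle members (permutation p = 1e-04, the smallest that 10000 permutations can give; the genes are not independent replicates). By sex the list means were uneven. Each sex held 1 control replicate and the males 1 replacement replicate, and the difference between sexes was not tested. In males the Paneth cell list, at 0.60, was close to the cell cycle list at 0.63. In females it was -0.90 against 0.94, while the stem cell list was 0.08 in males and 0.09 in females. The stem cell genes argue against an even increase only. A larger share of transit-amplifying cells, which are crypt cells too, or more division within a type stays open and was not tested, as does a rise of Paneth cells in males.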

How the results depend on the processing

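The alternatives with control 2 and control 3 as separate replicates, without a floor, with a pseudocount, with sex as a block and without control 2 and control 3 together were chosen after the data were seen. Over all alternatives the 107 called genes among the 192 named kept direction and call in 1539 of 2024 values, lost the call in 485 and reversed in 0. The 11 called lists kept it in 203 of 231 values, lost it in 28 and reversed in 0. The alternatives reuse the same arrays, so the lack of reversals lends no separate support. Among alternatives that left out no replicate, 19 of the 107 genes and 0 of the 11 lists kept the call in every one. Against 580 higher and 605 lower genes there were 70 and 92 with no filter, where more genes are tested and many sit at the floor (Cdh1 -1.06, adjusted p = 0.109). Scaling to the array medians gave 387 lower genes (Cdh1 -1.03, adjusted p = 0.0589), array weights 884 and 926, a test against 1.5-fold 169 and 127, no eBayes 12 and 20, separate control replicates 1118 and 1234, and no floor 348 lower. The replicate numbers do not pair the samples (correlations of deviations -0.017, -0.00082 and -0.055 for the same-numbered pairs), and with the replicate block 994 genes were higher and 1108 lower, and the PPAR-alpha and ketogenesis list (-0.37) had an adjusted p = 0.0599. Against 7 lists up and 4 down there were 0 and 0 with an estimated correlation and 5 and 1 with fry, which ended the calls of the cell cycle (adjusted p = 0.0626), receptor tyrosine kinase (0.0973), interferon (0.101), lipid absorption (0.302) and PPAR-alpha (0.0587) lists. Leaving out replicates gave 3 to 827 higher and 1 to 833 lower genes, Cdh1 differences of -1.21 to -0.92 and 3 to 7 lists down; the fewest genes were called without control 2 and control 3 together and the most without replacement 1. Where only 1 control replicate was left, it is assumed to vary like the others. Apart from the fewer samples and the larger set of genes, the cause was not tested. Cdh2 lay under the floor on every array and gives no value in any setting. The floor limits what dim transcripts can show: 32 higher genes had all control arrays, and 39 lower genes all replacement arrays, at it.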

Other observations

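Genes in the next paragraph were chosen after their values were seen and were tested for no enrichment as groups.

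Several genes of glucose handling differed. Slc2a1, a glucose transporter, rose from 79.3 to 611 (log2 difference 2.94, SE 0.326), and the hexokinases Hk1 (at least 2.74, SE 0.319, with 1 control array under the floor) and Hk2 (2.15, SE 0.279) rose with it, while Ldha, lactate dehydrogenase A, had 0.32 (adjusted p = 0.456). Pck1 (-1.99, SE 0.230), Fbp1 (-1.60, SE 0.271) and G6pc (-0.98, SE 0.222), enzymes of gluconeogenesis, were lower. Car9, a carbonic anhydrase, and the prolyl hydroxylase Egln3 rose by 2.38 (SE 0.269) and 2.03 (SE 0.226). Psat1 (2.16, SE 0.253), an enzyme of serine synthesis, rose, as did Gpx2 (2.59, SE 0.240) and Gsr (2.04, SE 0.347), which act in glutathione metabolism, and the exporters Abcc1 (2.09, SE 0.271), Abcc3 (2.35, SE 0.336) and Abcc4 (at least 2.38, SE 0.288, with 1 control array under the floor). Igf2, a fetal growth factor, was lower, from 442 to 75.3 (-2.55, SE 0.278), as were Maob (-2.25, SE 0.253) and Abca1, a cholesterol exporter (-2.02, SE 0.424).

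Some lists of other cell types differed between single replicates more than between the groups. The mean log2 intensity of 8 pancreatic acinar genes was 7.66 in control 1 and 5.35 in control 2 and control 3, and 5.24, 9.18 and 8.69 in replacement 1, 2 and 3. Fibroblast genes stood at 6.87 in control 1, 4.92 in the other control replicate and 5.53, 5.57 and 5.59 in the replacement replicates. MHC class II genes stood at 7.03 and 5.35 in the control and at 6.55, 5.39 and 5.13 in the replacement replicates. Within the samples read as female the difference of the MHC class II list was -1.77 and within those read as male 1.20, and for fibroblast genes -1.30 and 0.61. These sexes were read from the data, each holds 1 control replicate, the males hold 1 replacement replicate, and the difference between them was not tested.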
